A study of Homo sapiens with 5 samples.

How the data were processed

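RNA sequencing was analyzed for 5 libraries of the DLD-1 cell line, 2 controls and 3 treated with RK at 400 µg/mL for 72 h. They were grouped by the treatment label and numbered as the labels number them. For the controls no culture time is recorded here, and whether they received a vehicle was not established. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made by standard Illumina protocols; the strand setting, read length and pairing are not given in the sources used here. Reads were processed with TopHat2 2.1.0 and Cufflinks 2.2.1.0 on the human genome hg38, per the submitters' processing notes. The annotation version and the program that counted the reads are not given in the sources used here.

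The deposited tables hold, per the file headers, the exon positions, the summed exon length in nucleotides and 1 value for each of 56303 gene symbols. The deposited values are on the FPKM scale: in each library, value times length in kilobases adds up to 1000000, which the files themselves show. Within a library the values are multiples of a common step divided by length, and from that step the assigned reads were recovered as 19748507, 21175750, 23271687, 15825321 and 16097639 for control 1, control 2, RK 1, RK 2 and RK 3. Between 67% and 70.7% of the values above 0 came out as whole reads within a tolerance of 0.001, and at least 91.3% in any library were multiples of 0.01 read, so reads had been shared out in fractions and no test for whole counts was used. How far depth and the number of libraries each limit precision was not tested. In 28 rows the gene symbol had been turned into a date by spreadsheet software, and 17 of these rows were tested under that name and are not named here.

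Values were used as log2(FPKM + 1), without rescaling. Genes were kept with FPKM of 1 or more in at least 2 libraries and a length of at least 300 nt, which left 13584 genes and removed 42180 low and 539 short rows. A log2 fold change on this scale understates the change of low genes. RK was compared with control in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with trend and robust, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with all 5 libraries and no covariate and 3 residual degrees of freedom. An exact permutation of 2 against 3 libraries has 10 splits and cannot reach 0.05, so none was run. The design, the tests, the rule for named genes, 42 gene lists and the first set of alternatives were fixed before the data were examined. RK 2 and RK 3 were the closest pair (r = 0.995 across genes) but differed beyond counting noise. The chi-square per gene at 1 degree of freedom had a mean of 3.65 and a median of 0.948. They were kept as separate libraries, although this cannot tell separate cultures from repeat libraries of 1 culture.

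A split of the libraries into set A (control 1, RK 1) and set B (control 2, RK 2, RK 3) was found from the values. It follows the replicate numbers (1 against 2 and 3), whose meaning no label gives. It crosses the groups, so a second limma fit had the set as a term, with 2 residual degrees of freedom, and the RK change was also computed within each set. Gene lists of at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. In all, 37 lists were tested. With an estimated correlation, camera tests on the residual degrees of freedom of the fit, 3 without and 2 with the set term. Few lists could pass on so few, so a list not called there is left undecided. List symbols were matched to the tables directly or, for 35, by an older symbol in a RefSeq table (GRCh38.p14), and 783 of 788 matched. Some lists share members, such as FAS, MYC, SLC2A1 and SLC7A11.

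Named genes are those with adjusted p below 0.05, a log2 fold change of at least 1, FPKM of 5 or more in the higher group, no library at 0, groups that do not overlap and an official symbol, the 12 with the largest change in each direction. Where fewer pass, the fold and adjusted p criteria are both dropped and genes are ranked by p. The rule was applied to the planned fit, where no gene passed and ranking by p was used, and to the fit with the set term, where overlap was judged within each set; there 51 genes were eligible as higher and 7 as lower. Up to 4 members of each list with the smallest p, 20 key genes and the control genes were added. Of these, 3 genes are not reported here. A few further members that passed are named to complete a count.

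Gene positions are from the deposited tables on hg38. GENCODE 29 on the same build gave GC content for 11270 of the tested genes (83%); 98.2% of the 36027 symbols it shares with the tables lay at the same place. For GC correction, a natural spline with 5 degrees of freedom was fitted to each library across genes. Exon overlap between rows was computed with bedtools 2.31.1, and 7432 tested genes (54.7%) share some exon sequence with another row.

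Both fits were tested on simulated data with the observed set difference, over 13584 genes of which 200 were changed. Without the set term limma recovered 0 of 67 genes changed by 0.5 and 0 of 67 changed by 1 on the log2 scale, and 14 of 66 changed by 2. With the set term it recovered 53 of 67, 67 of 67 and 66 of 66, and 21 unchanged genes were called. These 21 are a larger share of all its calls than the adjusted p threshold aims for. The simulated sets were known and not found from the values, and each changed gene had a fixed size of change. In the real libraries the RK change often differed between the sets. The simulation therefore does not give the error rate of the calls made there. Alternatives were other scalings, pseudocounts, filters and variance models, array weights, a replicate block, leaving out each library and other list tests. The set term, set B alone, GC correction, removal of mitochondrial genes, voom weights and a trended variance in camera were added after the data were seen.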

Results

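The data were RNA sequencing profiles of DLD-1 cells, an epithelial line established from a human colorectal carcinoma. Raspberry ketone (RK), a phenolic aroma compound of raspberries, was given at 400 µg/mL for 72 h, and the profiles ask which transcripts differed between treated and control cells. There were 2 control and 3 RK libraries, each with an FPKM value (fragments per kilobase of transcript, scaled to the library total) for 56303 gene symbols. The number of reads assigned to genes, recovered from the steps between low values, was 19748507 in control 1 and 21175750 in control 2. It was 23271687 in RK 1, 15825321 in RK 2 and 16097639 in RK 3. In RK 2, with the fewest reads, 1 read on a transcript of 1 kb was worth 0.0632 FPKM. No label says whether the replicates were separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

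The intestinal keratin KRT20 and the cell cycle inhibitor CDKN1A were higher in each of the 3 RK libraries than in both control libraries, and MYC and the Wnt target AXIN2 were lower. KRT20, a marker of mature intestinal epithelium, was at 82.1 and 82.5 FPKM in the 2 control libraries and at 140, 164 and 164 FPKM in the 3 RK libraries. CDKN1A, which inhibits cyclin-dependent kinases, went from 3.99 and 1.46 FPKM to 29.8, 5.41 and 6.38 FPKM. MYC, a transcription factor that drives growth, went from 20.6 and 18.9 FPKM to 13.9, 12.6 and 13.4 FPKM. With limma and no covariate, the analysis fixed before the data were examined, none of these differences passed, and 0 of 13584 genes did (smallest adjusted p = 0.9998). An unadjusted p under 0.05 was reached by 423 genes, against 679 expected by chance, and limma with voom weights on the recovered reads also called 0 genes. Groups that did not overlap were seen for 18.7% of the genes, and chance gives 20%.

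The 5 libraries parted into 2 sets, those numbered 1 and those numbered 2 or 3, and no label says what the numbers stand for. Control 1 and RK 1 (set A) lay apart from control 2, RK 2 and RK 3 (set B) on the first principal component, which held 78.8% of the variance, while the second component, with 15.5%, separated RK from control. Mitochondrially encoded transcripts made up 3.42% and 2.04% of reads in control 1 and RK 1, and 11.3%, 10.9% and 10.9% in control 2, RK 2 and RK 3. Between the sets, 8473 genes (62.4%) differed in limma at the adjusted p threshold of 0.05. The sets were found from these same values, so this count describes the split and does not test it. Both sets hold control and RK libraries, so the RK change could be taken within each. The sets share no library, and across genes, which are not independent replicates, the RK change in set A correlated with that in set B (Pearson r = 0.628, Spearman rho = 0.6). It had the same sign in both sets for 71.7% of the genes. A change of 2-fold or more was found in 248 genes of set A and 44 of set B, and 28 were among both, 27 higher and 1 lower, where independent lists would share 0.6 higher genes. On the first component, RK also lay lower than control in both sets, at -51 against -28.7 in set A. In set B it was at 26.9 and 22.2 against 30.5. A shared step along the axis between the sets could give part of this correlation and overlap, which was not tested.

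**Figure D1:**
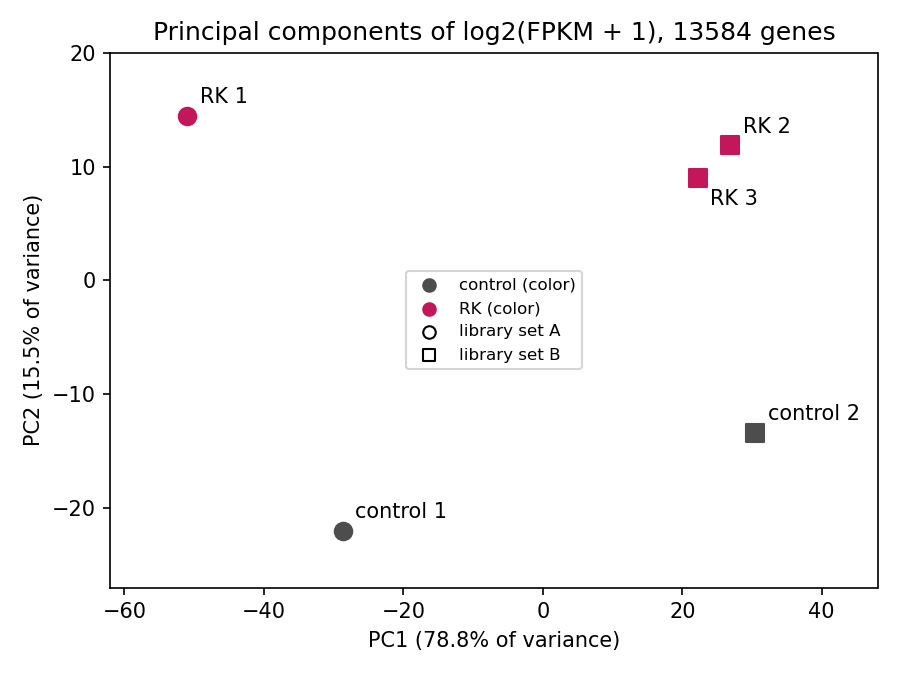
Principal components of log2(FPKM + 1) over 13584 genes, with one point per library, color for the group and shape for the library set; the axes give the share of variance. PC1, with 78.8% of the variance, separates set A (control 1 and RK 1) from set B, and PC2, with 15.5%, separates the 3 RK libraries from the 2 control libraries.

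With the library set as a term, chosen after the data were seen, limma called 1408 of 13584 genes (10.4%), 1050 higher and 358 lower with RK. In this fit an unadjusted p under 0.05 was reached by 4295 of the 13584 genes, against 679 expected by chance. Counts of list members at an unadjusted p, or adjusted over the list alone, are to be read against this background. Below, "rose", "fell" and "changed" refer to this fit, and values are log2 fold changes of FPKM + 1 ± SE over 2 control and 3 RK libraries. Of the 1408 genes, 86 changed at least 2-fold, 73 higher and 13 lower. The 2 residual degrees of freedom of this fit are the difference between RK 2 and RK 3 and the difference of the RK change between the sets. Each set has 1 control, so no SE or p-value of this fit holds a spread between controls of the same set. RK 2 and RK 3 may also be repeat libraries of 1 culture. The split of higher against lower calls differed between scalings, which also shift the center of the fold changes: 74.6% were higher with the deposited values, 59.3% (845 higher, 580 lower) with median-of-ratios scaling and 62.3% (667 and 403) with quantile normalization. After a correction for GC content, 53.1% of 2082 calls were higher (1106 higher, 976 lower). The number of calls was 311 without control 1, 2599 without control 2 and 226 without RK 1 (35, 242 and 35 at least 2-fold, and 163 at least 2-fold when all libraries were scaled to TPM), and 295 genes were called from set B alone. A block for the replicate number, an alternative fixed before the data were examined, leaves out RK 3, which has no control of its number, and gave 1156 genes. Set B alone, the block and each fit without 1 library have 1 residual degree of freedom. In set B alone, and without control 1, control 2 or RK 1, it is the difference between RK 2 and RK 3. It then holds no spread between controls, so these counts are not evidence of replication. With no filter on low values, 0 of 29802 genes passed in limma, although 4699 had an unadjusted p under 0.05.

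Of the genes that rose, 73 rose at least 2-fold. KRTAP3-1, a keratin-associated protein gene at chromosome 17, 41008521 to 41019324 (hg38), rose by 2.19 ± 0.20 (limma adjusted p = 0.00677), with 2.65 in set A and 1.85 in set B. MAOB, which encodes the mitochondrial amine oxidase monoamine oxidase B, rose 3.02-fold on the scale of FPKM + 1 (adjusted p = 0.00345). It went from 6.04 to 21.8 FPKM in set A and from 3.82 to 12.1 and 13.5 FPKM in set B. SERPINB5, a serpin known as maspin, rose 2.86-fold on the same scale (adjusted p = 0.00345). The elastase inhibitors PI3 and SLPI rose by 2.19 ± 0.50 and 1.41 ± 0.28, and their rise was 3.60 and 2.23 in set A against 1.13 and 0.79 in set B. S100P, a calcium-binding protein gene, rose by 2.65 in set A and 0.71 in set B (adjusted p = 0.0494 over both). RGS2, a regulator of G protein signalling, rose by 1.71 ± 0.28, PRR9 by 1.91 ± 0.25 and NOV, a matricellular protein gene, by 1.43 ± 0.12. PRSS2, a trypsinogen gene, rose by 1.88 ± 0.38, and this value is uncertain because trypsinogen paralogs share sequence. Among the genes with the smallest p without the set term, SERPINI1 (1.25 ± 0.12), COL17A1 (1.11 ± 0.09), SFN (1.10 ± 0.08), MUC13 (1.19 ± 0.09) and ENTPD3 (0.98 ± 0.11) rose. COL17A1 encodes a hemidesmosomal collagen, SFN the cell cycle regulator 14-3-3 sigma and MUC13 a transmembrane mucin.

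Fewer genes fell than rose, and 13 fell at least 2-fold. TXNIP, an inhibitor of thioredoxin, fell by 1.16 on the log2 scale (SE 0.21, adjusted p = 0.0247), from 13.4 to 3.31 FPKM in set A and from 8.05 to 4.46 and 4.49 FPKM in set B. SUPT4H1, a subunit of a transcription elongation factor at chromosome 17, 58345175 to 58353093, fell by 0.98 (SE 0.10). The antisense transcript TSPOAP1-AS1, which spans that locus on the other strand, fell by 0.72 (SE 0.09), with 61.3% of its exon length shared with other genes. HCFC1R1 and THOC6, overlapping neighbors on chromosome 16, fell by 1.15 (SE 0.12) and 0.92 (SE 0.11). Counting by strand is not stated, so reads from the shared parts cannot be assigned to 1 gene of either pair. The inositol trisphosphate receptor gene ITPR2 had a change of -0.85 ± 0.08, the golgin gene GCC2 -0.71 ± 0.07, the phosphodiesterase gene PDE4D -0.71 ± 0.09 and the serine palmitoyltransferase subunit gene SPTLC3 -0.77 ± 0.10. MIPEP, a mitochondrial peptidase gene, was at -0.70 ± 0.09 and SNTB1 at -0.73 ± 0.09, and all 6 of these genes fell.

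**Figure D2:**
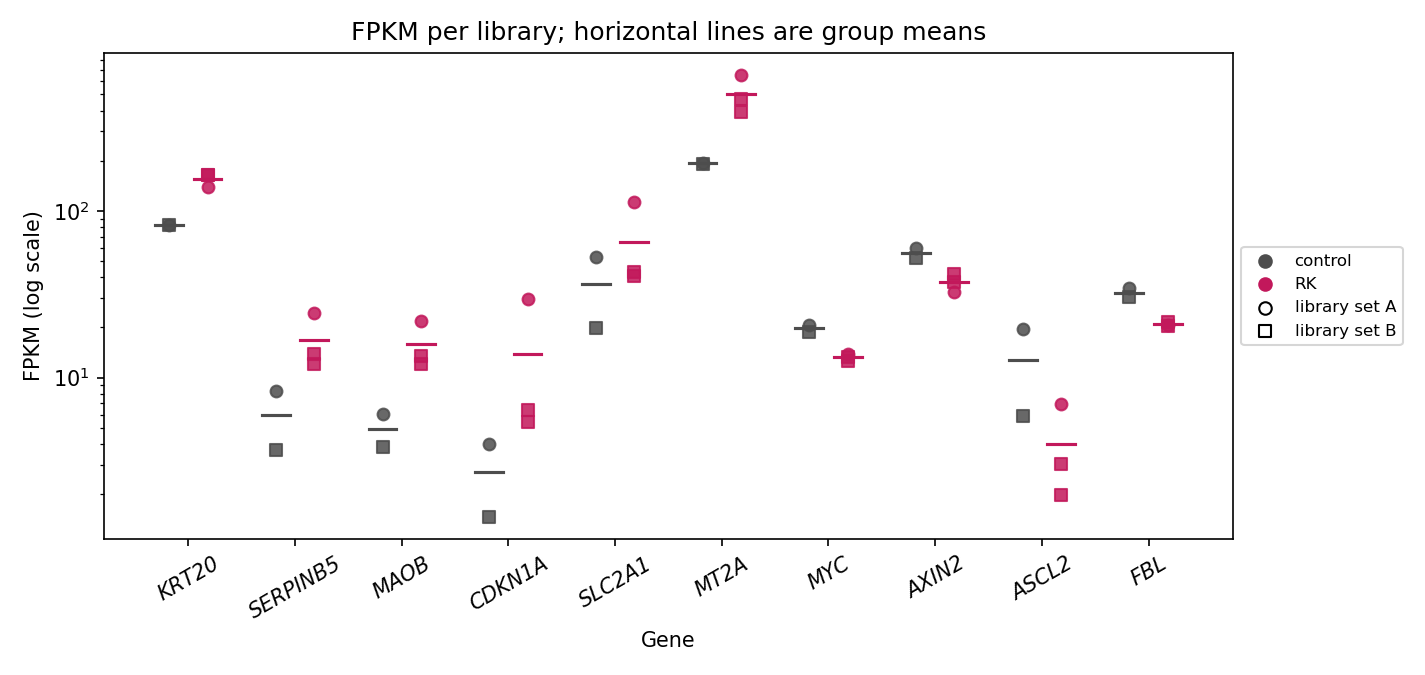
FPKM of 10 named genes (x axis) on a log scale (y axis), with one point per library, color for control or RK, shape for the library set and a horizontal line at each group mean. MYC lay between 18.9 and 20.6 FPKM in the control libraries and between 12.6 and 13.9 FPKM in the RK libraries, while SLC2A1 and ASCL2 separate by treatment within each set.

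Epithelial and intestinal markers rose in part. Of 10 colon epithelial markers, 4 rose, 0 fell and 6 did not pass, and 5 rose when adjusted over the list alone. They were the keratin genes KRT20 (0.89 ± 0.08), KRT18 (0.77 ± 0.09), KRT8 (0.62 ± 0.09) and KRT19 (0.56 ± 0.08). The list median was 0.46 in set A and 0.19 in set B, with a limma camera adjusted p = 0.00791, and adjusted p = 0.586 with an estimated correlation. Without the set term camera did not call it (adjusted p = 0.092). The library sets also differed in these markers, with 8 of the 10 lower in set B and 0 higher (median -0.66). Of 8 enterocyte genes, the tetraspanin TSPAN1 (0.91 ± 0.07), KRT20 and the carbonic anhydrase CA2 (1.01 ± 0.16) rose, and the alkaline phosphatase ALPP had a change of -0.48 ± 0.10 and fell. The counts were 3 higher and 1 lower adjusted over the list alone, and camera gave an adjusted p = 0.376. The trefoil factor TFF1 rose by 0.94 ± 0.12 and the mucin MUC5AC by 0.47 ± 0.08 among 4 goblet and secretory genes, too few for a list test, while TFF3 (0.96 ± 0.24) and AGR2 (0.23 ± 0.09) did not pass. MUC2, at most 0.147 FPKM, was not tested.

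Wnt target genes went both ways. The stem cell transcription factor ASCL2 fell by 1.16 (SE 0.15, adjusted p = 0.0149), from 19.6 to 6.91 FPKM in set A and from 5.92 to 1.98 and 3.02 FPKM in set B. AXIN2, a feedback inhibitor of Wnt signaling, was at -0.58 ± 0.12, TNFRSF19 at -0.56 ± 0.13 and MYC at -0.52 ± 0.07, and all 3 fell. CD44, a hyaluronan receptor gene, rose by 1.03 ± 0.11. Of 17 targets, 1 rose, 4 fell and 12 did not pass, 3 rose and 5 fell adjusted over the list alone, and camera gave an adjusted p = 0.33. The list median was 0.04, its mean -0.03 and the direction of its test lower, and the median was -0.03 with quantile normalization. LGR5 was at 2.73 and 2.64 FPKM in control and at 3.66, 2.84 and 2.56 FPKM in RK libraries, and CCND1 at 240 and 122 against 351, 160 and 136 FPKM; neither passed.

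Ribosomal and MYC-related lists were called lower by camera, with few single genes past the threshold unless GC content was corrected for. Of 29 cytosolic ribosomal protein genes, 0 rose and 1 fell, RPL5 (-0.38 ± 0.08), and 11 fell adjusted over the list alone. The median was -0.24 (-0.15 in set A, -0.29 in set B), and camera gave an adjusted p = 7.17e-08, but adjusted p = 0.586 with an estimated correlation. These genes have many processed pseudogenes that can take part of their reads, so the values are uncertain. Of 24 ribosome biogenesis genes, the nucleolar methyltransferase FBL (-0.60 ± 0.08) fell and 0 rose, with 5 lower adjusted over the list alone and a median of -0.26 in set A and -0.14 in set B. For that list camera gave an adjusted p = 2.26e-05, and adjusted p = 0.586 with an estimated correlation. MYC and C1QBP (-0.35 ± 0.08) fell among 18 MYC targets, 3 adjusted over the list alone, with medians of -0.2 and -0.07 in sets A and B (camera adjusted p = 0.000928; adjusted p = 0.586 with an estimated correlation). Without the set term camera called these 3 lists lower too (adjusted p = 5.4e-07, 0.00953 and 0.0162; adjusted p = 0.903 for each with an estimated correlation). After GC correction of the fit with the set term, 17 of the 29, 10 of the 24 and 4 of the 18 genes were called lower, and 24, 14 and 5 adjusted over the list alone; over the 11270 genes with a GC value 976 were called lower, against 358 of 13584 before.

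Transcripts induced by the EGFR and MAPK pathway rose in part. Of 21 measured genes, 10 rose, 0 fell and 11 did not pass, and 15 rose adjusted over the list alone. The MAPK phosphatase genes DUSP5 (1.20 ± 0.12) and DUSP6 (1.08 ± 0.08), the growth factor gene HBEGF (1.21 ± 0.19) and the AP-1 subunit gene FOSL1 (0.85 ± 0.12) were among them; for DUSP6, 40.5% of the exon length is shared with another gene. The median was 0.55 in set A and 0.38 in set B, with a camera adjusted p = 5.32e-05, and adjusted p = 0.586 with an estimated correlation. Without the set term camera did not call this list (adjusted p = 0.0818). Of 12 NF-kB and cytokine genes, 5 rose, 0 fell and 10 rose adjusted over the list alone, among them the cytokine gene IL18 (0.96 ± 0.08), NFKB2 (0.98 ± 0.08), CXCL8 (1.09 ± 0.19) and the cyclooxygenase gene PTGS2 (0.86 ± 0.16). Their median was 0.85 in set A and 0.35 in set B (camera adjusted p = 0.000841, and adjusted p = 0.586 with an estimated correlation). The library sets differed in these genes too, with 8 of the 12 lower in set B and 1 higher (median -0.97). Of 12 antigen presentation genes, 5 rose and 8 rose adjusted over the list alone, including HLA-B (1.01 ± 0.19), HLA-E (0.55 ± 0.09) and the peptide transporter TAP1 (0.57 ± 0.10). The median was 0.72 and 0.29 in sets A and B, and camera gave an adjusted p = 0.000928, or adjusted p = 0.586 with an estimated correlation; without the set term it did not call this list (adjusted p = 0.081). The library sets also differed in this list, with 11 of the 12 genes lower in set B. Reads of HLA genes can be shared among paralogs. Of 12 interferon response genes, IFI6 (1.02 ± 0.15), ISG15 (0.73 ± 0.12) and STAT2 (0.43 ± 0.10) rose, 5 rose and 1 fell adjusted over the list alone, and camera gave an adjusted p = 0.111.

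**Figure D3:**
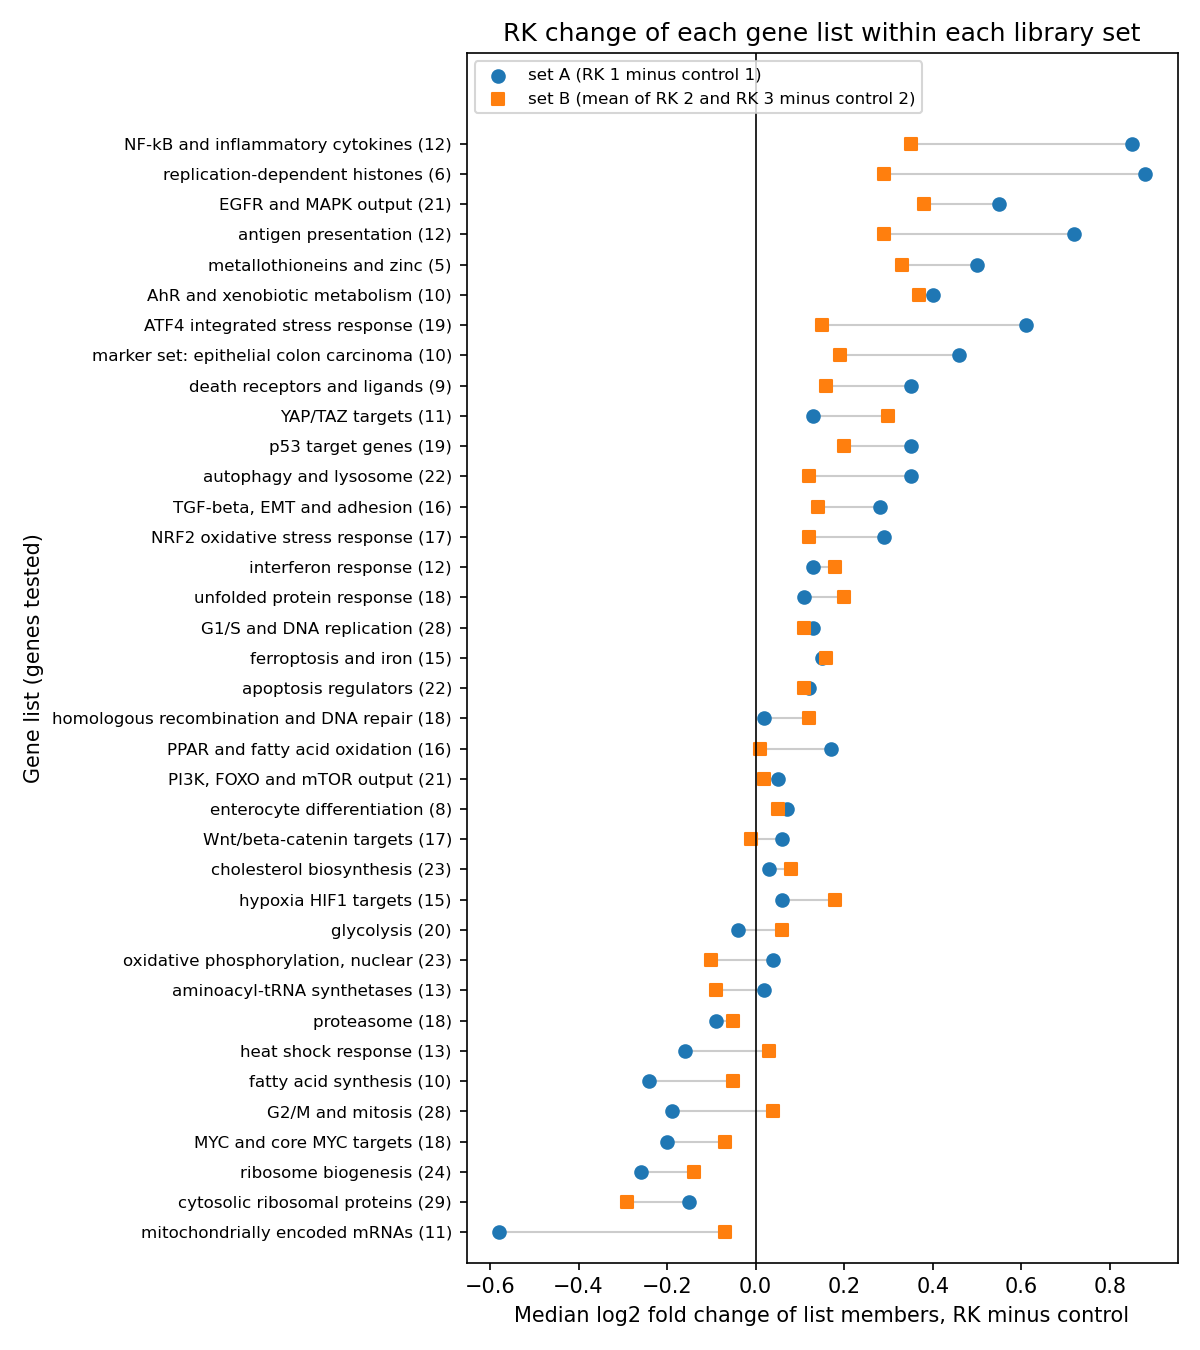
Median log2 fold change (x axis) of the tested members of each gene list (y axis, number of genes in brackets) within set A (circles, RK 1 minus control 1) and set B (squares, mean of RK 2 and RK 3 minus control 2). EGFR and MAPK output genes lie at 0.55 and 0.38, and mitochondrially encoded mRNAs at -0.58 and -0.07.

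Among stress responses, p53 target genes rose in part. CDKN1A rose by 1.97 ± 0.24 (2.63 in set A, 1.48 in set B; adjusted p = 0.0121), the cytokine gene GDF15 by 0.56 ± 0.09 and the death receptor gene FAS by 0.49 ± 0.09, while 16 of 19 targets did not pass. Adjusted over the list alone, 10 rose and 0 fell, and the median was 0.35 in set A and 0.20 in set B. Camera called the list higher (adjusted p = 0.00106; adjusted p = 0.586 with an estimated correlation). TNFRSF21, FAS and TNFRSF10A rose among 9 death receptor genes, 5 adjusted over the list alone, with medians of 0.35 and 0.16 in sets A and B (camera adjusted p = 0.00571; adjusted p = 0.586 with an estimated correlation). Of 22 apoptosis regulators, BIRC3 (0.63 ± 0.09) and MCL1 (0.36 ± 0.07), which restrain apoptosis, and PMAIP1 (0.89 ± 0.18) and BID (0.40 ± 0.10), which promote it, rose. These 4 also rose adjusted over the list alone, and camera gave an adjusted p = 0.214. BAX (0.17 ± 0.13) did not pass, and BCL2, at most 0.522 FPKM, was not tested.

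Antioxidant genes rose in part as well. Of 17 NRF2 targets, 7 rose, 0 fell and 10 did not pass, with 7 higher adjusted over the list alone. The quinone reductase NQO1 (0.63 ± 0.10), the thioredoxin reductase TXNRD1 (0.59 ± 0.10) and the cystine transporter SLC7A11 (0.49 ± 0.07) were among them. The median was 0.29 in set A and 0.12 in set B (camera adjusted p = 0.0158; adjusted p = 0.586 with an estimated correlation; not called without the set term, adjusted p = 0.271). HMOX1, at 1.94 and 0.88 FPKM in control and 3.25, 0.66 and 1.16 FPKM in RK libraries, did not pass. Of 10 xenobiotic metabolism genes, 4 rose, among them the aldehyde dehydrogenase ALDH3A1 (1.06 ± 0.11) and TIPARP (0.68 ± 0.09), and 6 rose and 1 fell adjusted over the list alone; CYP1A1 (-0.46 ± 0.17) did not pass. Camera called this list without the set term (adjusted p = 0.0165; adjusted p = 0.903 with an estimated correlation) but not with it (adjusted p = 0.0589). MT2A rose by 1.40 ± 0.15 and MT1X by 0.47 ± 0.10 among 5 metallothionein and zinc genes, 4 of which rose adjusted over the list alone. The median was 0.50 and 0.33 in sets A and B, and camera gave an adjusted p = 0.0312, or adjusted p = 0.586 with an estimated correlation. Reads may be shared among metallothionein paralogs.

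ATF3 (0.80 ± 0.18), CHAC1 (1.11 ± 0.24) and SLC7A11 rose among 19 genes of the ATF4 response, with 10 higher and 1 lower adjusted over the list alone; DDIT3 (0.34 ± 0.12) did not pass. The median was 0.61 in set A and 0.15 in set B (camera adjusted p = 0.0337; adjusted p = 0.685 with an estimated correlation; not called without the set term, adjusted p = 0.208). Of 18 unfolded protein response genes, 4 rose, including EDEM1 (0.42 ± 0.08) and DNAJB9 (0.50 ± 0.12), and 7 rose adjusted over the list alone. The chaperone gene HSPA5, at 448 and 553 FPKM in control and 402, 590 and 584.1 FPKM in RK libraries, did not pass. Its list had medians of 0.11 and 0.20 in sets A and B, and camera gave an adjusted p = 0.0421, or adjusted p = 0.586 with an estimated correlation; it did not call the list without the set term (adjusted p = 0.147) or after GC correction (adjusted p = 0.0549). HSPB1 (-0.76 ± 0.14) fell among 13 heat shock genes, 1 adjusted over the list alone (camera adjusted p = 0.0804). Of 22 autophagy and lysosome genes, 6 rose and 0 fell, 7 adjusted over the list alone, among them the galactosidase GLA (0.73 ± 0.08), the phosphoinositide effector WIPI1 (0.81 ± 0.10) and MAP1LC3B (0.66 ± 0.11). That list had medians of 0.35 and 0.12 in sets A and B (camera adjusted p = 0.000841; adjusted p = 0.606 with an estimated correlation).

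Neither cell cycle list passed camera. RRM2 (0.70 ± 0.08), CDC6 (0.59 ± 0.07), CCNE2 (0.90 ± 0.12) and CCNE1 (0.67 ± 0.09) rose and MCM7 (-0.35 ± 0.08) fell among 28 genes of the G1/S transition and DNA replication. Adjusted over the list alone, 9 rose and 5 fell, and camera gave an adjusted p = 0.152. Of 28 G2/M genes, CDK1 (0.47 ± 0.08) and AURKB (0.31 ± 0.07) rose, 1 adjusted over the list alone, and camera gave an adjusted p = 0.0622. The proliferation marker MKI67 was at 64.0 and 72.7 FPKM in control and at 52.7, 76.8 and 75.4 FPKM in RK libraries and did not pass. EXO1, RAD51AP1 and XRCC2 rose among 18 DNA repair genes, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.441). Of 6 replication-dependent histone genes, HIST1H2BK rose by 0.75 ± 0.16 and 5 rose adjusted over the list alone, with medians of 0.88 in set A and 0.29 in set B (camera adjusted p = 0.031; adjusted p = 0.586 with an estimated correlation).

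Among metabolic genes, the glucose transporter SLC2A1 rose by 1.06 ± 0.07 (adjusted p = 0.00418), by 1.08 in set A and 1.05 in set B. SLC16A3 (0.56 ± 0.09), PFKP (0.45 ± 0.08), ENO2 (0.50 ± 0.10) and HK1 (0.31 ± 0.07) also rose among 20 glycolysis genes, 5 of which rose adjusted over the list alone (camera adjusted p = 0.62). CPT1A (0.73 ± 0.12) and ACADVL (0.64 ± 0.08), enzymes of fatty acid oxidation, rose with ANGPTL4, and ACAA2 (-0.38 ± 0.08) fell, among 16 genes. There, 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.376), and PPARGC1A, at most 0.182 FPKM, was not tested. SC5D and TM7SF2 rose among 23 cholesterol synthesis genes, 3 adjusted over the list alone (camera adjusted p = 0.786); HMGCS1 (-0.57 ± 0.19) did not pass. Of 10 fatty acid synthesis genes 0 passed in limma over all genes and 4 had an unadjusted p under 0.05, and 1 rose and 2 fell adjusted over the list alone. Camera called this list lower only without the set term (adjusted p = 0.0468; adjusted p = 0.903 with an estimated correlation), and with the term it gave an adjusted p = 0.112. SLC2A1, P4HA2, ANGPTL4 and P4HA1 rose and EFNA1 fell among 15 hypoxia targets, 7 and 1 adjusted over the list alone (camera adjusted p = 0.44).

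Of 11 mitochondrially encoded mRNAs, 0 passed in limma, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05, and the median was -0.58 in set A and -0.07 in set B. Camera called them lower with the set term (adjusted p = 0.00102; adjusted p = 0.586 with an estimated correlation) and not without it (adjusted p = 0.866). Of 23 nuclear genes of oxidative phosphorylation, 18 proteasome genes and 13 aminoacyl-tRNA synthetase genes, 0 passed in limma and 0 adjusted over the list alone. An unadjusted p under 0.05 was reached by 2, 4 and 5 of them, and by 4295 of all 13584 genes. Camera gave adjusted p = 0.152, 0.0588 and 0.251 for these lists. Their members with the smallest p were SDHB (-0.22 ± 0.08), PSMC1 (-0.24 ± 0.08) and LARS (-0.28 ± 0.08). TGFBI, an extracellular matrix protein gene induced by TGF-beta, rose by 1.21 ± 0.07 (adjusted p = 0.00345), and the tight junction gene CLDN1 (1.09 ± 0.16) and the integrin gene ITGB4 (0.61 ± 0.09) rose too, while CLDN2 (-1.04 ± 0.22) fell. Of these 16 adhesion and TGF-beta genes 7 rose and 2 fell adjusted over the list alone, with medians of 0.28 and 0.14 in sets A and B (camera adjusted p = 0.0421; adjusted p = 0.61 with an estimated correlation; not called without the set term, adjusted p = 0.552, or after GC correction, adjusted p = 0.0549).

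The YAP/TAZ targets CTGF (0.61 ± 0.12) and AMOTL2 (0.33 ± 0.07) rose among 11, 7 rose and 1 fell adjusted over the list alone, and camera gave an adjusted p = 0.228. Of 15 ferroptosis and iron genes 4 rose, among them FTL (0.38 ± 0.08), and STEAP3 (-0.40 ± 0.09) fell, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.173). SESN3 (0.55 ± 0.10), FOXO3 (0.39 ± 0.08), KLF6 (0.47 ± 0.10) and AKT1 (0.35 ± 0.08) rose and TXNIP fell among 21 PI3K, FOXO and mTOR genes, 4 and 2 adjusted over the list alone (camera adjusted p = 0.739). Markers of other cell types were low: no fibroblast marker exceeded 0.333 FPKM, KDR was the only endothelial marker tested (at most 1.45 FPKM) and CD68 the only leukocyte marker (at most 4.96 FPKM). CD68 rose by 1.04 ± 0.19, with 85.8% of its exon length shared with other genes. Of 13 control genes, GUSB rose by 0.74 ± 0.14 and 12 did not pass, with 2 higher adjusted over the list alone. Over all lists, camera called 11 of 37 without the set term (7 higher, 4 lower) and 17 with it (13 higher, 4 lower). With an estimated correlation it called 0 in either fit (smallest adjusted p = 0.903 and 0.586). That version tests on only 3 and 2 residual degrees of freedom, so these 0 calls decide nothing about the lists. For death receptors with the set term, the estimated correlation was -0.079, and for unfolded protein response genes -0.011, both under the preset 0.01. The unadjusted camera p of death receptors still went from 0.00154 to 0.0812. For the other called lists the estimate, from the same few degrees of freedom, was above the preset. It was 0.045 for EGFR and MAPK output, 0.475 for NF-kB genes, 0.705 for cytosolic ribosomal proteins, 0.833 for ATF4 genes and 0.902 for mitochondrially encoded mRNAs. Where members are correlated above 0.01, the preset makes the camera p too small. Fry, which asks whether a list's genes move on balance one way, called 0 lists without the set term and 2 with it, enterocyte genes (adjusted p = 0.0219) and G1/S genes (adjusted p = 0.0443). After GC correction fry called neither of these (adjusted p = 0.111 and 0.15), and the enterocyte median went from 0.04 to -0.05. It then called 5 other lists: epithelial markers (adjusted p = 0.00162), EGFR and MAPK output (adjusted p = 0.011), NRF2 targets (adjusted p = 0.0127), death receptors (adjusted p = 0.0326) and ferroptosis and iron genes (adjusted p = 0.0377).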

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

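Alternatives that use the library set were chosen after the data were seen. Without the set term, limma called 0 genes under every planned scaling, pseudocount, filter and variance model, with array weights and without any 1 library, and 0 also without mitochondrial genes, with GC correction and with voom weights. With the set term it called 1408 genes (86 at least 2-fold), and from set B alone 295 (35 at least 2-fold). The replicate numbers 1 and 2 are shared by both groups, but no label says that they pair libraries. As a replicate block they gave 1156 genes, 90 at least 2-fold, and 19 lists. RK 3 has no control of its number and drops out of the block, so this is the fit with the set term without RK 3, and not a separate model. In deviations from the group means, same-numbered libraries went together (r = 0.87 and 0.823 across genes), and RK 3 went with control 2 (r = 0.78). The deviations of the 2 controls are opposite by construction, and those of the 3 RK libraries cancel out. These correlations therefore restate the split into sets and do not test a pairing by number. Of the 1156 genes, 962 were among the 1408 called with RK 3.

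Starting from 1408 genes, the fit with the set term gave 786 with short features kept, 586 with array weights, 3136 with voom weights and 0 with no filter. The median total degrees of freedom was 6.9, and 4.4 with no filter, where 29802 instead of 13584 genes were tested. The cause of these differences was not tested. Without 1 library it gave 226 to 2599 genes, the lowest without RK 1 and the highest without control 2. From 86 genes at least 2-fold it gave 163 scaled to TPM, 195 and 218 with pseudocounts of 0.1 and 0.01, 56 at FPKM of 5 or more, 57 with array weights, 264 with voom weights, 0 with no filter and 35 to 242 without 1 library. A lower pseudocount enlarges folds of low genes by construction; for the others the cause was not tested.

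Camera lists, 11 without the set term, were 17 with it, 7 with no filter, 4 with array weights, and 5 to 18 without 1 library (5 without RK 1, 18 without control 1). With an estimated correlation they were 0, and with fry 0. With the set term the 17 lists became 0 with an estimated correlation and 2 with fry, and ranged from 14 to 20 otherwise; without 1 library they ranged from 14 to 19. The cause was not tested.

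Of 263 named genes, 139 were called with the set term, and 0 reversed a called direction under any alternative. Of these 139, 139 were still called scaled to TPM, 134 after GC correction, 124 with median-of-ratios scaling, 114 with quantile normalization, 62 without RK 1 and 0 with no filter. Array weights did not reach their convergence tolerance in 1 fit. Filtering on estimation status and summing by symbol instead of gene ID were not run, because the tables have no status column and 1 entry per symbol; camera does not use the eBayes settings. With the set term, leaving out control 1 or RK 1 leaves the RK change to set B, and leaving out control 2 leaves it to 1 control and 1 RK library of set A, assumed to vary like the others. Genes with FPKM of 1 or more in fewer than 2 libraries are untested because of the filter, not the depth of 15825321 to 23271687 reads.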

Other observations

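The tests of GC content and depth for the library sets, both tests of the higher and lower calls, and the reassignment of libraries were chosen after the result was seen; the test on mitochondrial genes and those on the EGFR and MAPK genes were written before.

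The 2 library sets differed in genes of several lists. All 11 mitochondrially encoded mRNAs were higher in set B than in set A in limma, with a list median of 2.23 on the log2 scale, and all 21 EGFR and MAPK output genes were lower, with a median of -0.96. Of 19 ATF4 response genes 18 were lower (median -0.90), of 17 NRF2 targets 15 (median -0.69), of 15 hypoxia targets 13 (median -0.79) and of 12 antigen presentation genes 11 (median -0.89). Of 13 control genes 9 were lower too and 0 higher (median -0.35). The median-of-ratios factors were 1.104 and 1.188 in control 1 and RK 1, and 0.905, 0.916 and 0.942 in control 2, RK 2 and RK 3. A typical gene was therefore lower in set B on the FPKM scale. The counts and medians between the sets are not corrected for this shift, and how much of them it makes up was not tested. Ribosome biogenesis genes were higher in 11 of 24 and lower in 1 (median 0.20), and G2/M genes higher in 11 of 28 and lower in 5 (median 0.12). Camera called 16 lists between the sets, and 0 with an estimated correlation (smallest adjusted p = 0.695), while fry called 26 of 37 (smallest adjusted p = 0.00563). Because the sets were found from the same values, these counts and p-values describe the sets and do not test them. S100P was lower in set B by 3.09 on the log2 scale and the glucose transporter SLC2A1 by 1.39, given as changes of -3.09 and -1.39. Across genes, the RK change and the set difference had a correlation of -0.336, part of which arises because both are estimated from the same libraries.

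Among the classes of gene tested, 1125 of 10318 protein-coding genes (10.9%) were called in the fit with the set term, 22 of 433 pseudogenes (5.1%) and 42 of 494 other RNA genes (8.5%).

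The libraries part into 2 sets along an axis that crosses the treatment. GC-dependent coverage was tested as the whole cause, since the set difference followed GC content across genes (r = -0.488): after GC correction the first component still held 69.8% of the variance (bootstrap over genes 68.8% to 70.7%), against 79.7% before on the same genes, which argues against it as the only source. Leaving out mitochondrial genes gave 76% (75.4% to 76.8%), which argues against their share of the total. Sequencing depth did not order the sets, since 1 library of set B, control 2, lay between both libraries of set A. Separate culture times, RNA preparations or sequencing runs stay open, because the labels record none, and no biological explanation was tested.

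More genes were higher than lower with RK in the fit with the set term (74.6% of calls). The share was 59.3% with median-of-ratios scaling and 53.1% after GC correction. Both settings center the fold changes (median -0.009 and -0.014 against 0.044 on the log2 scale), which shifts the balance of calls by itself, and after GC correction there were more lower calls (976 against 358), and no fewer higher ones (1106 against 1050), on 11270 instead of 13584 genes. These shares therefore decide nothing about scaling, GC-dependent coverage or an excess of induced genes with RK, and all 3 stay open.

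The rise of EGFR and MAPK output genes with RK, with a list median of 0.49, was set against the axis between the sets because these genes also differed between the sets. After the regression of the RK change on the set difference was removed, the median was 0.28, with a bootstrap interval of 0.09 to 0.43 that includes the bound of 0.1 fixed for this explanation, so the set axis and a response to RK cannot be told apart for this list. GC correction left a median of 0.43 (0.20 to 0.55), which argues against GC-dependent coverage as the whole cause. The set axis was not tested for the other lists that also differed between the sets, such as antigen presentation genes, and stays open for them.

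For the count of 1408 genes, treatment was reassigned within the sets in every way that keeps 1 RK library in set A and 2 in set B. Of 6 assignments, 1 gave as many genes, the real one, and the highest of the others gave 0. With 6 assignments the share cannot fall under 0.05.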
